A study of Mus musculus with 6 samples.

How the data were processed

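The series holds 3 single-nucleus multiome libraries of C57BL/6J mouse retina, 1 for each of a naïve control, WIF1 at 2 weeks and WIF1 at 4 weeks. The times carry the abbreviation AVI, which the labels do not expand. The design names a pair of Wif1 vectors, with and without a GFP reporter, and does not state which was used here. It gives 2 eyes per group and does not state whether they were pooled. A control vector is named in the design, and 0 of the libraries come from eyes given it. The spatial data of the series were not analysed here.

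The deposited matrices hold raw counts, RNA UMIs per gene and ATAC counts per peak for each called barcode, per the file headers. Per the submitters' processing notes they were made with Cell Ranger ARC 2.0.1 on mm10 (GRCm38.p6), and Seurat 5.0.1 and Signac 1.12.0 are named without their roles. Peaks were called separately in each library, so the peak lists differ between libraries. All 32285 genes were read from the files with the symbols and Ensembl identifiers they pair.

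Nuclei were kept with at least 500 UMIs, at least 300 genes and at most 10% mitochondrial UMIs. The lowest barcode held 500 UMIs in the control, 7 at 2 weeks and 300 at 4 weeks, and 0, 3400 and 294 barcodes were under 500 UMIs. Doublets were scored with the Scrublet method in scanpy. Its automatic threshold called 0, 316 and 0 doublets and was not used. The score threshold was set instead at an expected rate of 0.8% per 1000 barcodes, which called 511, 1053 and 716 of the 7683, 9901 and 9637 nuclei that passed the filters.

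Counts were scaled to 10000 per nucleus and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 gave clusters of all 3 libraries together. A cluster was named as rod-like, bipolar-like and so on from fixed marker genes when 3 markers of the class were enriched, and a sub-cluster needed 4. It stayed unnamed all the same if another class had as many markers enriched or more markers among the 10 leading genes, or if over 50% of its nuclei were called doublets. By these limits sub-clusters 14.5 (5 amacrine markers, with 9, 2 and 0 kept nuclei), 20.3 (4 amacrine markers, with 4, 8 and 4), 21.0 (5 Müller markers, with 16, 5 and 13) and 21.3 (6 Müller markers, with 1, 18 and 11) stayed unnamed, as did cluster 31 with 9 cone markers, of whose nuclei 100% were called doublets. The sub-cluster minimum and a rule that sets immunoglobulin-rich sub-clusters aside were chosen after the data were seen. They kept 1, 20 and 0 nuclei (sub-cluster 13.2), 28, 2 and 0 nuclei (sub-cluster 14.4) and 8, 6 and 6 nuclei (sub-cluster 21.2) of the control, 2-week and 4-week libraries out of the named classes. In all 176, 85 and 56 nuclei (2.45%, 0.961% and 0.628%) stayed unnamed. Shares are of named nuclei, with Clopper-Pearson intervals, and their ratios have conditional binomial intervals.

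Expression was summed over the nuclei of a class in a library and given as CPM of the class total, for classes of at least 50 nuclei in each library compared and genes of at least 30 UMIs in the higher library. CPM have exact Poisson intervals and ratios have conditional binomial intervals. A group at 0 was set to a floor of 3 counts over the class, and such a ratio is written as at least N-fold. Ratios that rest on 1 to 3 counts are given with their interval or as the counts. No gene was tested, because cells of 1 library are not replicates. Median depths of rod-like, bipolar-like and Müller-like nuclei were 1160, 3761 and 3485 UMIs in the control, 695, 2345 and 2469 at 2 weeks, and 1025, 3263 and 3481 at 4 weeks.

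The named-gene rule took, for Müller-like, rod-like and bipolar-like nuclei, the 5 genes with the highest and the 5 with the lowest ratio among those of at least 30 UMIs and 50 CPM in the higher library, without mitochondrial and sex-linked genes and, outside rods, rod-list genes. A library under 3 UMIs was set to 3 for this ranking. Members of the lists at 2-fold or more with at least 30 UMIs could be named too, and Wif1, Tcf4 and Tcf7l2 always were. Genes named below 2-fold as members of a list, such as B2m and H2-K1 at 4 weeks, were chosen after their values were seen. Gene lists were fixed by hand. A list is summarised by the median log2 ratio of its members with at least 10 UMIs over the pair of libraries, an order-statistic interval over members, and its percentile among 10000 random lists matched on expression. The samples, the groups, the lists, the named-gene rule and most alternatives were fixed before the data were examined.

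Promoters were peaks within 1000 bp of a gene's start, with at least 30 counts in the higher library, scaled to CPM of all promoter counts. Promoter peaks of the 15352 genes with one in all 3 libraries covered 12.8, 13.5 and 13.1 Mb, with means of 1972, 4436 and 3674 counts per kb. Rod chromatin in a nucleus was estimated from peaks of rod-like nuclei, and RNA of rod origin in another class, free or from mixed droplets, from rod genes.

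The ratios were tested on simulated counts with 2-fold and 4-fold differences placed in them. These counts carried counting error alone, without UMIs gathered in few nuclei, free RNA or mixed droplets. Unchanged genes past 2-fold may therefore be more frequent in the real libraries than in the numbers below. At 2 weeks, genes past 2-fold were 38 of 78 placed at 2-fold and 85 of 85 placed at 4-fold in Müller-like nuclei, with 58 of 5305 unchanged genes also past it. In rod-like nuclei these were 46 of 94, 99 of 99 and 11 of 10403, and in bipolar-like nuclei 40 of 99, 100 of 100 and 30 of 11583. At 4 weeks they were 35 of 89, 84 of 84 and 98 of 7415 in Müller-like, 56 of 99, 96 of 96 and 15 of 10724 in rod-like, and 46 of 92, 94 of 94 and 10 of 11622 in bipolar-like nuclei. Of lists of 20 genes drawn from those placed 2-fold higher, which share genes, 50 of 50 lay above the 97.5th percentile in each class and comparison. The interval of their median held the true value in 31 of 50 in endothelial-like nuclei at 2 weeks. It did so in 44 of 50 in rod-like nuclei at 4 weeks and in 49 or 50 elsewhere.

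The alternatives covered scaling, depth, mitochondrial share, doublets, clustering, free RNA, rod chromatin, and peak and promoter rules. A planned motif comparison was not run, because it needs the genome sequence. The calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.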

Results

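Nuclei of C57BL/6J mouse retina were assayed by single-nucleus multiome sequencing, which reads the RNA and the open chromatin (ATAC) of the same nucleus. The 3 groups were a naïve control, WIF1 overexpression at 2 weeks and WIF1 overexpression at 4 weeks, with 1 library and 2 eyes per group. WIF1 is a secreted protein that binds Wnt ligands, and it was delivered by an AAV2/2 vector. The libraries held 8556 barcodes in the control, 13528 at 2 weeks and 10334 at 4 weeks. RNA counts came to 21805441, 14568384 and 19997276 unique molecular identifiers (UMIs), and ATAC counts to 37525307, 90490537 and 71304238. After filtering, 7172, 8848 and 8921 nuclei were kept, with median RNA depths of 1635, 800 and 1200 UMIs. The median share of mitochondrial UMIs per kept nucleus was 1.88% in the control, 0.519% at 2 weeks and 0.600% at 4 weeks. With 1 library per group there were no replicates, so each difference is a description of these libraries. The intervals given are 95% intervals that cover counting error alone, except those of list medians, which run over list members. The control eyes were naïve, so injection, vector and WIF1 differ from the control together.

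The first question was whether Wif1 RNA was higher in the libraries from treated eyes. Wif1 (ENSMUSG00000020218, mm10 chromosome 10, 121034004 to 121100642) was higher in both WIF1 libraries, at a low level. Kept nuclei held 1 Wif1 UMI in the control, 11 at 2 weeks and 37 at 4 weeks, or 0.0578, 0.966 and 2.22 as counts-per-million (CPM) values. The ratio to control was 16.7 (2.43 to 719) at 2 weeks and 38.3 (6.47 to 1554) at 4 weeks, and the 4-week value was 2.29 times (1.15 to 4.98) that at 2 weeks. At 4 weeks bipolar-like nuclei held 19 of these UMIs (3.33 CPM, 2.00 to 5.19) and Müller-like nuclei 10 (8.13 CPM, 3.90 to 14.9). A few nuclei carried most of them, since 5 nuclei held 89.5% of the Wif1 UMIs of the bipolar-like class. Over all barcodes the UMIs were 3, 17 and 40, with ratios to control of 8.48 and 14.5, and a ratio of 4 over 2 weeks of 1.71 (0.95 to 3.22). The assay reads the 3' end of transcripts, so RNA from a vector cassette without the native 3' end may be missing from these counts.

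At the promoter of the endogenous Wif1 gene the order of the libraries depended on the scale and the class. Counts in its promoter peak were 10.2 (9.05 to 11.4), 10.7 (9.89 to 11.5) and 7.34 (6.67 to 8.06) CPM of all ATAC counts in the control, 2-week and 4-week libraries. Ratios to control were 1.05 (0.918 to 1.21) and 0.723 (0.623 to 0.839), and the peak was called with lengths of 810, 915 and 930 bp. Per 1000 nuclei, a scale not corrected for ATAC depth, the counts were 42.9, 75.3 and 49.1. The ratios to control were then 1.75 (1.53 to 2.01) and 1.14 (0.986 to 1.33), the latter with an interval that holds 1. As CPM of promoter counts within a class, ratios at 2 and 4 weeks were 1.57 (1.26 to 1.95) and 0.895 (0.702 to 1.14) in bipolar-like, 1.17 (0.894 to 1.55) and 1.17 (0.896 to 1.55) in rod-like, and 1.51 (0.769 to 3.19) and 0.684 (0.350 to 1.44) in Müller-like nuclei, where the first was 0.862 without nuclei of over 25% rod chromatin. Cone-like nuclei stood at 14.4, 12.6 and 4.78 CPM of all ATAC counts and amacrine-like nuclei at 12.4, 16.8 and 4.08, the last from 3 counts. Peaks at 121040702 to 121041518 and at 121055369 to 121056309, both inside the gene, were called in the 2-week library alone. The first held 62 counts, 50 of them in bipolar-like nuclei, and the other held 48, of which 24 were in Müller-like nuclei. The 2-week library had the most ATAC counts, and the other libraries hold no counts outside their own peaks.

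**Figure D1:**
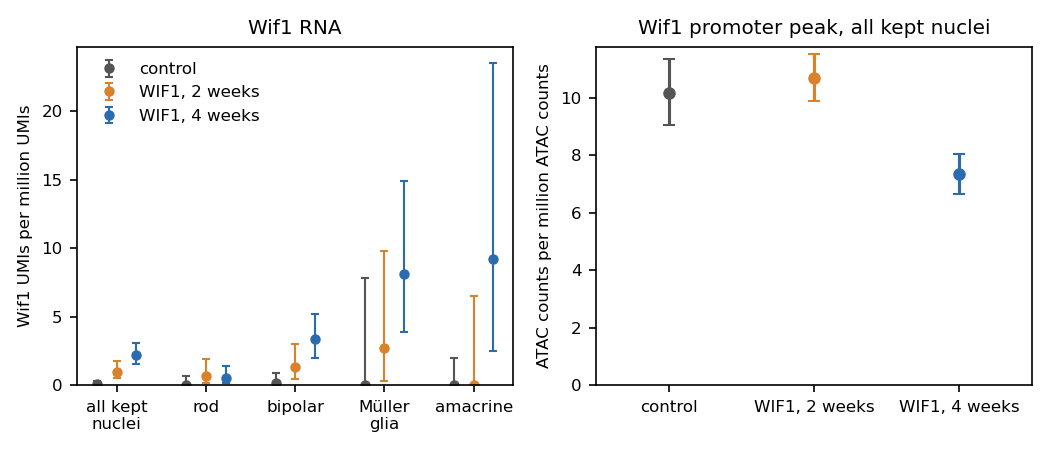
Wif1 RNA in CPM in all kept nuclei and in 4 cell classes (left), and counts in the Wif1 promoter peak in CPM of all ATAC counts (right), with 95% Poisson intervals. RNA in all kept nuclei was 0.0578 in the control, 0.966 at 2 weeks and 2.22 at 4 weeks, while the promoter, pooled over classes, was lowest at 4 weeks, at 7.34.

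The make-up of the retina was compared next, from clusters named by marker genes. Amacrine-like nuclei, inhibitory interneurons of the inner retina, made up 5.20% (4.69 to 5.75) of named nuclei in the control, 2.42% (2.11 to 2.76) at 2 weeks and 1.26% (1.04 to 1.52) at 4 weeks. Their share was 0.465 times the control share (0.391 to 0.552) at 2 weeks and 0.243 times (0.195 to 0.301) at 4 weeks, or 0.701 and 0.577 times with nuclei named by their highest marker score. Müller-like nuclei, the radial glia of the retina, were 1.87% (1.57 to 2.22), 3.23% (2.87 to 3.62) and 2.94% (2.60 to 3.32). Microglia- or macrophage-like nuclei were 0.200%, 0.662% and 0.169%, so that the 2-week share was 3.31 times (1.82 to 6.42) the control share. A lymphocyte-like cluster held 22 nuclei (0.251%) at 2 weeks and 0 in the other libraries.

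Rod-like nuclei were 61.4%, 68.4% and 70.4% of named nuclei, with ratios to control of 1.11 (1.07 to 1.16) and 1.15 (1.10 to 1.19). Bipolar-like nuclei were 23.8%, 18.4% and 18.8%, with ratios of 0.774 (0.723 to 0.830) and 0.789 (0.737 to 0.845). Cone-like nuclei were 5.42%, 5.32% and 4.93%, with ratios of 0.982 (0.855 to 1.13) and 0.910 (0.791 to 1.05). Endothelial-like nuclei numbered 68, 55 and 77, and pericyte- or smooth muscle-like nuclei 48, 43 and 55. Horizontal-like nuclei numbered 25, 20 and 0, and 25, 20 and 5 with called doublets kept. Retinal ganglion-like nuclei were rare, with 8 of 6996 in the control (0.114%), 0 of 8763 at 2 weeks, which allows a share of up to 0.0342% by a limit of 3 counts, and 1 of 8865 at 4 weeks. Shares compare classes within a library, and several of these ratios moved with the processing. Among nuclei of at least 1000 UMIs, a floor that 729 of 5991 rod-like and 198 of 212 amacrine-like nuclei met at 2 weeks and 3029 of 4296 and 359 of 364 in the control, the ratio at 2 weeks was 0.944 for amacrine-like, 0.412 for rod-like, 1.60 for bipolar-like, 2.02 for cone-like and 3.43 for Müller-like nuclei, and with each library clustered alone the Müller-like ratios were 1.04 and 0.866. Of nuclei other than rods, the bipolar-like ratio at 4 weeks was 1.03.

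**Figure D2:**
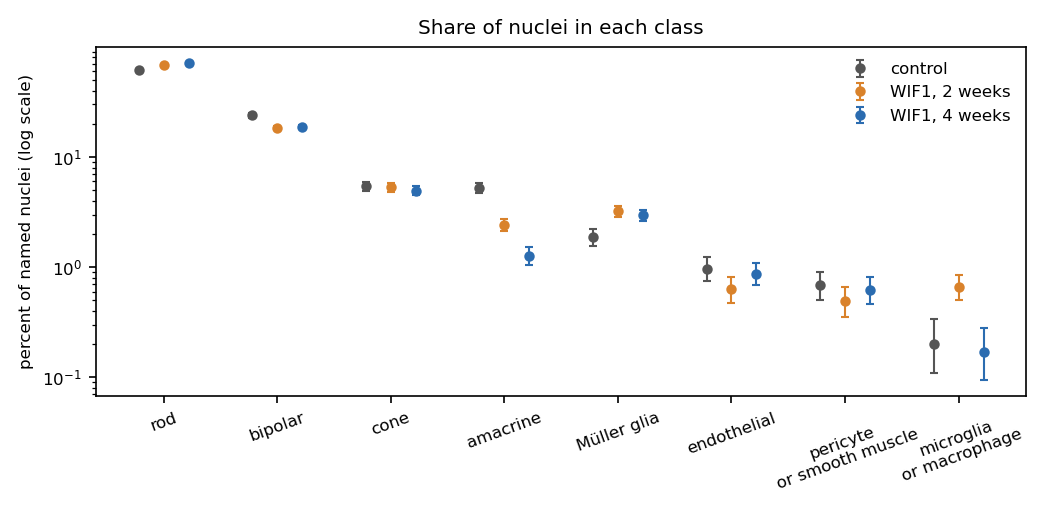
Share of named nuclei in each class per library, in percent on a log axis, with 95% Clopper-Pearson intervals. Amacrine-like shares were 5.20%, 2.42% and 1.26% in the control, 2-week and 4-week libraries, and the microglia- or macrophage-like share was highest at 2 weeks, at 0.662%.

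Among amacrine-like nuclei the clusters differed in how much lower their share was. Cluster 14, whose amacrine-like sub-clusters were mostly enriched for the GABA-synthesis genes Gad1 or Gad2, held 151 nuclei in the control, 37 at 2 weeks and 18 at 4 weeks, with share ratios of 0.196 (0.133 to 0.282) and 0.0941 (0.0543 to 0.154). Its sub-clusters with Gad1 held 41, 6 and 1 (14.1), 15, 1 and 0 (14.2), 24, 20 and 9 (14.6), 14, 6 and 8 (14.10) and 12, 4 and 0 nuclei (14.12), and those with the glycine transporter gene Slc6a9 held 30, 0 and 0 (14.3, also with Gad2) and 15, 0 and 0 (14.7). Over the nuclei in cluster 14, Gad1 stood at 443, 627 and 491 CPM and Slc6a9 at 155, 27.3 and 34.2 CPM. Cluster 20, with the transcription factor gene Ebf3 and Slc6a9, held 94, 82 and 38 nuclei, with ratios of 0.696 (0.512 to 0.947) and 0.319 (0.213 to 0.470). Cluster 22, with the gap junction gene Gjd2 and Slc6a9, held 119, 93 and 56 nuclei, with ratios of 0.624 (0.470 to 0.825) and 0.371 (0.265 to 0.514). Another sub-cluster, which expressed the amacrine marker genes Slc6a9, Slc32a1 and Pax6, was left unnamed under a rule on sub-clusters set after the data were seen, and it held 28, 2 and 0 nuclei. Sub-cluster 14.5, with Gad1 and Gad2, stayed unnamed because of a marker of another class, and it held 9, 2 and 0. Cluster 14 held 280, 50 and 27 kept nuclei when its retinal ganglion-like and unnamed nuclei are counted too. Sub-clusters with the same amacrine markers also differed by library in opposite ways, so sub-cluster counts alone do not show that a type was lost.

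**Figure D3:**
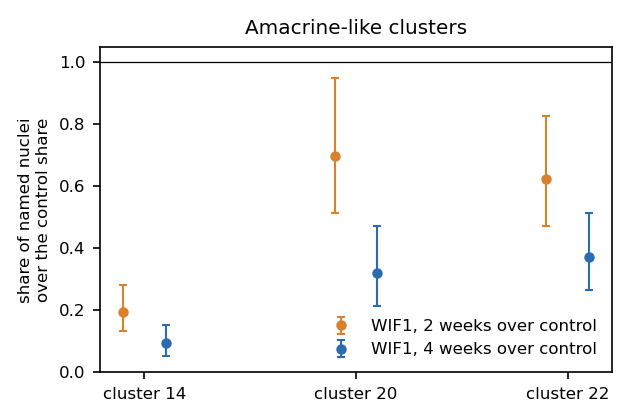
Share of named nuclei in each of 3 amacrine-like clusters divided by the control share, with 95% conditional binomial intervals and a line at 1. Cluster 14 had the lowest ratios, 0.196 at 2 weeks and 0.0941 at 4 weeks.

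The comparison of the 2-week library with the control asks how each retinal class differed early after WIF1 delivery. Genes of antigen presentation were higher in the 2-week library, by their median, in each of the 6 classes measured. In rod-like nuclei free RNA from other cells was not told apart from their own RNA. In bipolar-like nuclei B2m (ENSMUSG00000060802), the light chain of MHC class I, was 20.1-fold higher (14 to 29.7) and the class I gene H2-K1 (ENSMUSG00000061232) was 13.2-fold higher (10.9 to 16.1). Müller-like nuclei also had more RNA of reactive-glia genes, led by Lcn2 (ENSMUSG00000026822), a lipocalin of inflamed glia, at 19.9-fold higher (9.49 to 50.1). RNA of cholesterol synthesis enzymes was lower in the same nuclei.

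The antigen presentation list had a median log2 ratio of 2.85 (0.76 to 3.91) in bipolar-like nuclei, where 20 of 21 measured members were higher. In Müller-like nuclei its median was 2.10 (1.55 to 2.64) with 20 of 21 members higher, in rod-like nuclei 2.30 (0.19 to 3.43) with 14 of 18, and in cone-like nuclei 2.15 (0.42 to 3.25) with 10 of 10. Amacrine-like nuclei gave 1.73 (−0.27 to 3.57), with 8 of 11 members higher, and endothelial-like nuclei 0.51 (0.23 to 1.33), with 12 of 13. H2-K1 was 6.24-fold higher in Müller-like (4.91 to 8.04), 7.12-fold in rod-like (4.35 to 12.3), 5.93-fold in cone-like (4.28 to 8.38) and 5.66-fold in amacrine-like nuclei (4.14 to 7.79). B2m was 5.98-fold higher in Müller-like nuclei, at 1282 against 214 CPM, 10.7-fold in rod-like and 7.97-fold in amacrine-like nuclei. The class I genes H2-Q6 and H2-Q7 were also higher in bipolar-like nuclei, H2-Q6 at least 53.6-fold against a control of 0 UMIs and H2-Q7 34.7-fold (17.2 to 81.8). Among genes of peptide processing, the immunoproteasome genes Psmb8 and Psmb9 were 11.2-fold and 7.20-fold higher there, as was the class I activator Nlrc5, at 7.20-fold (3.27 to 18.0). Cd74 (ENSMUSG00000024610), the class II invariant chain, held 134 UMIs against 1 in rod-like nuclei and 69 against 1 in Müller-like nuclei, where 1 nucleus held 33.3% of them.

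Interferon response genes were higher in 4 of these classes. The list's median log2 ratio was 1.28 (1.03 to 1.59) in bipolar-like nuclei with 30 of 34 members higher, 1.19 (0.94 to 1.63) in Müller-like nuclei with 38 of 41, 1.08 (0.46 to 1.90) in rod-like nuclei with 19 of 21 and 1.31 (0.43 to 3.14) in amacrine-like nuclei with 15 of 16. Cone-like and endothelial-like nuclei gave 0.23 (−0.85 to 1.13) and 0.16 (−0.33 to 0.46). In Müller-like nuclei the interferon-induced gene Oasl2 was 2.94-fold higher and the interferon regulatory factor gene Irf9 3.10-fold. Among bipolar-like nuclei, cluster 11 held 33.7%, 35.6% and 36.2% in the control, 2-week and 4-week libraries, and cluster 18 held 3.37%, 1.67% and 0.541%.

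Müller-like nuclei carried the reactive-glia list at a median log2 ratio of 0.93 (0.55 to 1.40), with 26 of 28 members higher. Serpina3n, a protease inhibitor of reactive astrocytes, was 17.1-fold higher (6.48 to 63.8), and Gfap, the intermediate filament of reactive glia, 4.68-fold (44 against 6 UMIs). Clu, a secreted chaperone, was 2.82-fold higher (2.68 to 2.97), at 10549 against 3740 CPM. Cebpd, a transcription factor of the acute phase, was 2.90-fold higher and Osmr, a receptor of oncostatin M, 2.63-fold (1.69 to 4.25). The complement list had a median of 1.23 (−0.65 to 3.05) with 8 of 11 members higher, among them C4b at 10.0-fold, C3 at 8.30-fold and the C1 inhibitor gene Serping1 at 7.88-fold (5.19 to 12.5). Müller homeostasis genes had a median of 0.14 (−0.15 to 0.50), with 14 of 22 higher. Cholesterol synthesis genes had a median of −1.20 (−1.57 to −0.32), with 16 of 18 lower, including Msmo1 at 2.97-fold lower (2.00 to 4.48) and Sqle at 3.55-fold lower (1.88 to 7.01). In the control 42.7% of Müller-like nuclei had over 25% of rod chromatin, against 14.5% at 2 weeks and 20.7% at 4 weeks, and without such nuclei the reactive-glia median was 0.51.

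By the rule fixed for named genes, which ranks genes of at least 50 CPM in the higher library, the 5 highest genes of Müller-like nuclei were Lcn2, Serpina3n, Cd74, the class I gene H2-Q7 (61 against 1 UMI) and the immediate early gene Fos (57 against 2 UMIs), for which 1 nucleus held 56.1%. The 5 lowest were neuronal or photoreceptor genes and a gene model, Ppef2 (26.6-fold lower, 8.61 to 133), Lrrtm4 (24.3-fold), Gm19667 (24.3-fold), Galntl6 (45 UMIs in the control against 1) and Ntng1 (41 against 3). In the control 5 nuclei held 95.2% of the Lrrtm4 UMIs of this class. Rod phototransduction genes had a median log2 ratio of −2.31 (−2.69 to −2.08) in Müller-like nuclei and of −1.02 (−1.29 to −0.85) in bipolar-like nuclei, with 35 of 35 members lower in each. With RNA of rod origin subtracted the bipolar-like median was 0.30, over members with at least 10 UMIs left. That value is a ratio of what the subtraction left and says little about the direction. RNA of rod origin, free or from mixed droplets, which were not told apart, was estimated at 28.0% of Müller-like UMIs in the control, 6.60% at 2 weeks and 30.5% at 4 weeks, and at 14.9%, 6.67% and 9.39% of bipolar-like UMIs. Less of it in a class can raise the CPM of other genes there. Müller-like ratios at 2 weeks, such as those of Clu and H2-K1, may hold such a part.

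Edn2, Fgf2, Stat3 and Cebpd were among the genes higher in rod-like nuclei. Edn2, an endothelin that injured photoreceptors make, was 23.9-fold higher (13.1 to 48.7) in the 2-week library, the growth factor gene Fgf2 2.48-fold (1.93 to 3.21) and the transcription factor gene Stat3 2.76-fold (2.41 to 3.17). Cebpd was 6.70-fold higher (4.82 to 9.51), and Gnb3, the G protein beta subunit of cones and ON bipolar cells, 3.88-fold (3.5 to 4.30). The reactive-glia list had a median log2 ratio of 1.19 (0.05 to 2.22) in rod-like nuclei, with 16 of 19 members higher, and complement genes gave 1.1 (−0.10 to 2.92). Rod phototransduction genes had a median of −0.14 (−0.21 to 0.01), with 23 of 35 lower. Among genes of at least 50 CPM, those of this class ranked above Cebpd were immunoglobulin genes with 0 UMIs in the control, Igkc (at least 734-fold higher), Igha (at least 138-fold), Ighg2c (at least 133-fold) and Ighm (at least 121-fold). The 5 lowest were Gm42418 (14.3-fold lower) and AY036118 (14-fold), both transcripts at ribosomal RNA sequence, and Hist3h2a (3.38-fold), Tpt1 (3.05-fold) and Cmss1 (2.84-fold). Rod-like nuclei lay in the same clusters in different proportions, with cluster 6 holding 32.1%, 5.44% and 9.99% of them in the control, 2-week and 4-week libraries and cluster 0 holding 6.52%, 47.7% and 17.3%. Cluster 3, which has Edn2, Fgf2 and Cebpd among its leading genes, held 1.77%, 16.7% and 4.24%.

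Among genes of at least 50 CPM, bipolar-like nuclei had Igkc (at least 815-fold higher, 50.9% of its UMIs in 1 nucleus), Ighg2c (at least 510-fold), B2m, H2-K1 and H2-D1 (5.92-fold, 4.92 to 7.15) as their 5 highest genes. AY036118 (12.8-fold lower), Gm42418 (11.7-fold), the photoreceptor disc gene Prcd (2.81-fold), Gm42439 (2.52-fold) and the actin regulator gene Wipf3 (2.27-fold) were their 5 lowest. Immediate early genes had a median log2 ratio of 0.63 with 14 of 17 higher, among them Egr1 at 2.26-fold (1.80 to 2.84), against 0.57 in rod-like, 0.77 in Müller-like and 0.04 in amacrine-like nuclei. Ribosomal protein genes had medians of −0.66 in rod-like, −0.24 in bipolar-like and −0.76 in Müller-like nuclei, and mitochondrially encoded genes −1.59, −0.55 and −1.38, while among nuclei of at most 1% mitochondrial UMIs the ribosomal median in bipolar-like nuclei was 0.39. Cone phototransduction genes gave 0.09 in cone-like nuclei. In rod-like, bipolar-like and Müller-like nuclei the medians were 0.04, 0.06 and 0.29 for cell death genes, 0.30, 0.20 and 0.45 for ganglion cell injury genes and −0.38, −0.19 and −0.15 for heat shock genes.

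The Wnt lists address the pathway that WIF1 binds. Wnt/β-catenin target genes had median log2 ratios near 0 in the 2-week library, at 0.15 (−0.28 to 0.93) in Müller-like nuclei with 10 of 16 higher, 0.25 (−0.18 to 0.63) in rod-like, −0.00 (−0.50 to 0.25) in bipolar-like with 11 of 22 higher, and −0.12 in amacrine-like nuclei. Wnt ligands, receptors and carriers gave 0.58 (−0.13 to 0.94) in Müller-like nuclei with 11 of 15 higher, −0.10 in rod-like and −0.17 in bipolar-like nuclei, and the Müller-like value was 0.00 without nuclei of over 25% rod chromatin. Wnt signal transduction genes gave 0.26 (−0.02 to 0.47) in bipolar-like nuclei, 0.16 in Müller-like and 0.15 in rod-like nuclei. Extracellular Wnt inhibitors gave 0.18 in Müller-like nuclei with 5 of 7 higher and 0.14 in bipolar-like nuclei with 4 of 7. Tcf4 (ENSMUSG00000053477) was 1.42-fold higher in Müller-like (1.26 to 1.60), 1.10-fold in bipolar-like (1.05 to 1.15) and 1.24-fold in amacrine-like nuclei (1.14 to 1.36), and its ratio was 0.936 in rod-like nuclei (0.868 to 1.01). It is the gene of an E-box transcription factor and is distinct from Tcf7l2, though the Wnt signal transduction list holds it. Tcf7l2, a nuclear effector of Wnt signalling, had a ratio of 1.17 (0.957 to 1.43) in Müller-like nuclei. The Müller-like ratios of Tcf4 and Tcf7l2 given here are not corrected for RNA of rod origin. It was estimated at 28.0% of Müller-like UMIs in the control and 6.60% at 2 weeks, and part of these ratios may come from that difference. Among nuclei of at most 1% mitochondrial UMIs the log2 ratio of Tcf4 in bipolar-like nuclei was −0.16.

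The comparison of the 4-week library with the control asks the same of the later time. Antigen presentation and interferon genes were near or below their control levels in most classes. Lcn2 remained high in Müller-like nuclei, at 20.5-fold (9.83 to 51.2), with 46.8% of its UMIs in 1 nucleus. Reactive-glia genes as a list were close to the control there, and cholesterol synthesis genes were lower in 17 of 22 cases.

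Antigen presentation had a median log2 ratio of −0.28 in rod-like nuclei with 4 of 11 members higher, −0.26 in bipolar-like with 5 of 14, −0.18 in Müller-like with 6 of 14, −0.16 in cone-like with 2 of 8 and 0.19 in amacrine-like nuclei. In bipolar-like nuclei the log2 ratio was −0.05 for B2m and −0.17 for H2-K1, and in Müller-like nuclei 0.27 and −0.33, while B2m was 1.84-fold higher in rod-like nuclei (1.06 to 3.33). Interferon response genes gave −0.02 in rod-like, −0.01 in bipolar-like and −0.14 (−0.43 to 0.16) in Müller-like nuclei, and 0.55 (−0.23 to 1.10) in amacrine-like nuclei with 8 of 10 higher. In bipolar-like nuclei of at most 1% mitochondrial UMIs the antigen presentation median was 0.55.

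In Müller-like nuclei the reactive-glia list had a median of 0.17 (−0.22 to 0.94), with 16 of 29 members higher, against 0.11 in rod-like and 0.01 in bipolar-like nuclei. C4b was 3.96-fold higher (1.72 to 11.2), Serpina3n 3.73-fold (1.35 to 14.4) and Gfap 2.11-fold (0.871 to 6.15). Complement genes gave 0.27 in Müller-like, 0.05 in rod-like and −0.10 in bipolar-like nuclei. Cholesterol synthesis genes had a median of −0.35 (−0.58 to −0.09), or −0.042 as a mean over nuclei, and Müller homeostasis genes −0.15. The 5 highest genes of at least 50 CPM were Lcn2, the chemokine gene Ccl2 (at least 19.0-fold higher, with 135 of 149 UMIs in 1 nucleus), the adhesion gene Cntn5 (79 against 1 UMI), the potassium channel partner gene Dpp10 (5.68-fold, 2.51 to 15.9) and Trnp1 (5.21-fold, 2.13 to 16.5). The 5 lowest were the laminin gene Lama2 (3.42-fold lower, 1.99 to 5.93), the cone genes Gngt2 (3.30-fold) and Pde6h (3.05-fold), the mitochondrial import gene Timm8b (2.53-fold) and Psmb8 (2.53-fold). Without nuclei of over 25% rod chromatin the log2 ratio of Cntn5 was −0.97, and with the counts of each nucleus thinned to 1000 those of Trnp1 and Psmb8 were −0.55 and 0.45.

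Of genes of at least 50 CPM, rod-like nuclei had Antxr2 (2.14-fold higher, 1.85 to 2.48), B3galt1 (1.72-fold), the vesicle transport gene Rab21 (1.58-fold), the mitochondrial iron importer gene Slc25a37 (1.53-fold) and Mafg (1.51-fold) as their 5 highest genes. Gm42418 (2.18-fold lower), Smim40 (2.09-fold), Pde6h (1.92-fold), the translation elongation factor gene Eef2 (1.92-fold) and Gpx4, which reduces lipid peroxides (1.89-fold), were the 5 lowest. Edn2 was 2.28-fold higher (1.1 to 5.0) and the planar polarity gene Vangl2 3.35-fold (1.66 to 7.45). Rod phototransduction genes had a median log2 ratio of −0.14 (−0.25 to −0.02) in rod-like nuclei with 25 of 35 lower, −0.63 in bipolar-like and 0.04 in Müller-like nuclei.

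Of genes of at least 50 CPM, bipolar-like nuclei had Ccdc85a (1.66-fold higher, 1.39 to 1.99), 9330182L06Rik (1.54-fold), the neuregulin receptor gene Erbb4 (1.43-fold, 1.35 to 1.51), the chromatin reader gene Brd9 (1.43-fold) and the TGF-beta effector gene Smad4 (1.42-fold) as their 5 highest genes. Vitronectin (Vtn, 2.11-fold lower, 1.82 to 2.44), Prcd (2.07-fold), the cadherin gene Fat4 (2.03-fold), the adhesion gene Ncam2 (1.95-fold) and the calcium-binding gene Cabp2 (1.94-fold) were the 5 lowest. Fat4 and Ncam2 are leading genes of cluster 18, which held 56 nuclei in the control and 9 at 4 weeks. Immediate early genes had a median log2 ratio of −0.32 (−0.95 to 0.06) with 12 of 17 lower, including Egr1 at 2.5-fold lower (1.78 to 3.57), and in amacrine-like nuclei −0.75 (−1.18 to −0.12) with 11 of 13 lower. The complement factor gene Cfi was 2.85-fold higher (1.88 to 4.41), and the heat shock gene Hspa1b 3.41-fold lower (1.73 to 7.33). Among nuclei of at most 1% mitochondrial UMIs the log2 ratio of Cabp2 was 0.41.

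Over rod-like, bipolar-like and Müller-like nuclei in that order, the 4-week medians were −0.60, −0.46 and −0.39 for ribosomal protein genes and −1.07, −0.60 and −0.86 for mitochondrially encoded genes. Among nuclei of at most 1% mitochondrial UMIs the ribosomal medians were 0.084 in bipolar-like and 0.051 in Müller-like nuclei, and the mitochondrial median in Müller-like nuclei was 0.042. The 4-week medians were −0.37, −0.01 and −0.21 for heat shock genes, the last of them 0.081 without nuclei of over 25% rod chromatin, 0.16, −0.10 and −0.12 for cell death genes, and −0.08, −0.19 and −0.01 for ganglion cell injury genes. Immediate early genes gave 0.14 in rod-like and 0.27 in Müller-like nuclei, and cone phototransduction genes −0.05 in cone-like nuclei.

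Wnt/β-catenin target genes at 4 weeks had medians of 0.28 (−0.26 to 0.61) in Müller-like nuclei with 11 of 19 higher, −0.03 in rod-like, −0.08 in bipolar-like and 0.01 in amacrine-like nuclei. The Müller-like median lay at percentile 98.6 among random lists of matched expression, and it was −0.33 among nuclei of at most 1% mitochondrial UMIs. Wnt ligands, receptors and carriers gave 0.05 in Müller-like, −0.03 in rod-like and −0.26 in bipolar-like nuclei, and the ligand gene Wnt5b was 2.38-fold higher in Müller-like nuclei (1.17 to 5.48), with a log2 ratio of −0.28 after thinning to 1000 UMIs per nucleus. Wnt signal transduction genes gave 0.12 (0.09 to 0.19) in rod-like nuclei with 23 of 30 higher, 0.07 in bipolar-like and 0.11 in Müller-like nuclei. Extracellular Wnt inhibitors gave −0.16 in Müller-like and 0.04 in bipolar-like nuclei. Tcf4 was 1.21-fold higher in rod-like (1.14 to 1.29) and 1.05-fold in bipolar-like nuclei (1.01 to 1.09), where its log2 ratio was −0.11 among nuclei of at most 1% mitochondrial UMIs, and its ratio in Müller-like nuclei was 1.08 (0.962 to 1.21). Tcf7l2 had ratios of 1.30 (0.968 to 1.75) in rod-like and 0.834 in Müller-like nuclei.

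**Figure D4:**
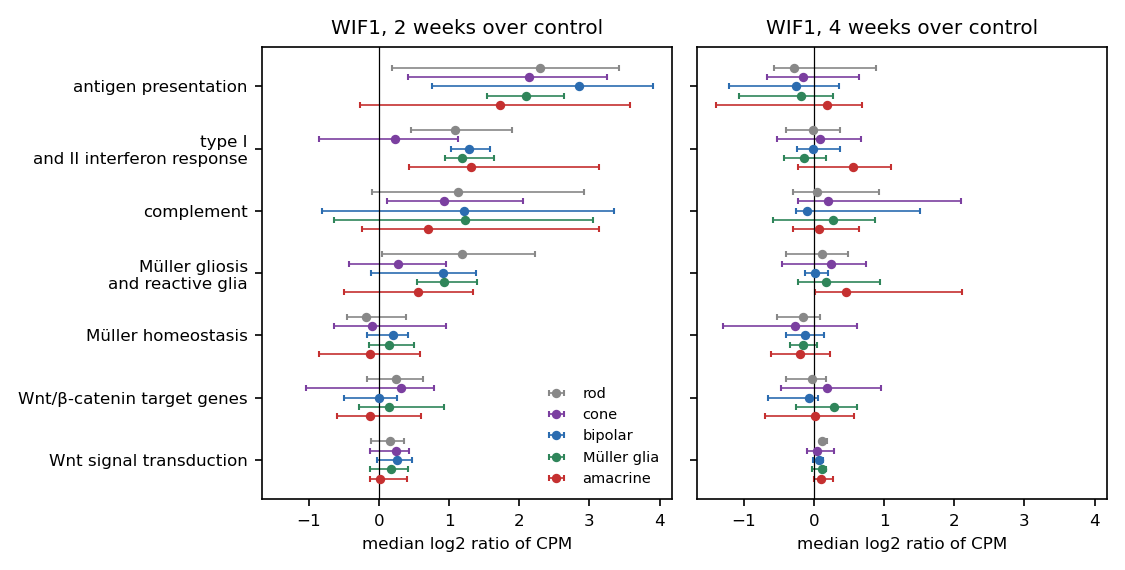
Median log2 ratio of CPM to control for 7 gene lists in 5 classes, at 2 weeks (left) and 4 weeks (right), with 95% intervals over list members. At 2 weeks antigen presentation reached 2.85 in bipolar-like nuclei, and at 4 weeks it was −0.26 there, while Wnt/β-catenin target genes were at −0.00 and −0.08.

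The direct comparison of 4 weeks with 2 weeks places the immune genes at the earlier time. Antigen presentation genes were lower at 4 weeks in bipolar-like (−3.15, −4.02 to −0.82), Müller-like (−2.85, −3.06 to −1.59), rod-like (−2.29, −3.41 to −0.52) and cone-like nuclei (−1.97, −3.29 to −0.41), as median log2 ratios. All 19 measured members were lower in rod-like nuclei, as were 19 of 21 in bipolar-like and 20 of 21 in Müller-like nuclei. Interferon response genes gave −1.29 (−1.67 to −0.97) in Müller-like nuclei with 40 of 41 lower, −1.26 (−1.68 to −0.66) in bipolar-like and −1.19 (−2.17 to −0.45) in rod-like nuclei, where members of at least 30 UMIs gave −0.37. In Müller-like nuclei the reactive-glia list gave −0.62 (−1.09 to −0.40), cholesterol synthesis genes 0.48 (0.26 to 1.19) with 19 of 21 higher, and Wnt/β-catenin target genes −0.41 (−0.74 to 0.22). Without nuclei of over 25% rod chromatin the reactive-glia value was −0.09.

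Open chromatin was compared through the peaks called in each library and through the promoters of the same genes. The libraries had 54429, 103911 and 75686 peaks that covered 46.0, 89.1 and 64.5 Mb in the control, 2-week and 4-week libraries. Of the control peaks 86.7% overlapped a 2-week peak and 86.0% a 4-week peak, while 45.5% of the 2-week peaks and 61.9% of the 4-week peaks overlapped a control peak. The number of peaks followed the order of ATAC depth, with medians of 3281.5, 6300 and 5589 counts per kept nucleus. Peaks missing from the control list are therefore not shown to be closed there. Promoters of antigen presentation genes were more accessible in the 2-week library in bipolar-like nuclei, with a median log2 ratio of 0.58 (0.12 to 0.77) and 17 of 20 higher, in cone-like nuclei, with 0.44 (0.09 to 1.19) and 14 of 16, and in Müller-like nuclei, with 0.97 (0.21 to 1.67) and 16 of 18. In rod-like nuclei their median was −0.12 (−0.36 to 0.13), and in amacrine-like nuclei 0.37 (−0.06 to 1.41). Peaks at these promoters covered 20.2, 21.8 and 21.3 kb, and per covered kb the medians at 2 weeks were 0.12 (−0.02 to 0.63) in bipolar-like, 0.92 in cone-like and 0.99 in Müller-like nuclei. Restricted to peaks shared by all 3 libraries, the bipolar-like median was 0.58 (0.10 to 0.72).

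Single promoters of these lists differed by class. In bipolar-like nuclei of the 2-week library the promoter of H2-Q6 was 2.94-fold higher (2.44 to 3.57), H2-Q4 2.51-fold (2.05 to 3.10) and Nlrc5 2.34-fold (1.80 to 3.07). Müller-like nuclei had 3.64-fold more counts (2.22 to 6.34) at the promoter that Psmb9 shares with the peptide transporter gene Tap1, and 2.32-fold more at B2m. In rod-like nuclei the promoters of Irf1, an interferon-induced transcription factor (2.96-fold, 2.17 to 4.13), and of Cebpd (2.60-fold, 2.04 to 3.36) were higher, while that of H2-Q6 had a ratio of 0.26. Interferon response promoters had medians of 0.53 (0.27 to 0.63) in bipolar-like nuclei with 28 of 32 higher, 0.56 (0.47 to 1.11) in Müller-like, 0.35 in cone-like and 0.01 in rod-like nuclei. These promoters were covered by 32.0, 34.8 and 32.7 kb of peaks, and per covered kb the bipolar-like median was 0.47 (0.10 to 0.54). Without nuclei of over 25% rod chromatin the Müller-like interferon median was 0.25.

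At 4 weeks antigen presentation promoters had medians of −0.07 in bipolar-like, −0.08 in Müller-like, −0.04 in cone-like and −0.19 (−0.65 to −0.01) in rod-like nuclei. Interferon response promoters gave −0.12 in bipolar-like, −0.23 (−0.42 to −0.07) in Müller-like and −0.17 in rod-like nuclei, and the Müller-like value was 0.16 without nuclei of over 25% rod chromatin. Promoters of Wnt/β-catenin target genes had medians of 0.43 (−0.49 to 1.0) in Müller-like, 0.22 in rod-like and 0.15 in bipolar-like nuclei at 2 weeks. The Tcf4 promoter had ratios of 1.32 (0.888 to 1.99) and 1.36 (0.955 to 1.99) in Müller-like nuclei, or 2.27 (1.04 to 5.84) and 3.0 (1.37 to 7.78) without nuclei of over 25% rod chromatin, from 7 control counts, 1.10 (1.02 to 1.20) and 1.17 (1.08 to 1.27) in rod-like nuclei, and 0.867 (0.761 to 0.988) and 1.0 in bipolar-like nuclei, at 2 and 4 weeks.

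Across genes, log2 ratios of promoter counts and of RNA were weakly related. At 2 weeks Pearson's r was 0.016 over 9786 genes in rod-like, 0.029 over 10681 in bipolar-like and 0.361 over 4990 in Müller-like nuclei, with Spearman's rho of −0.01, 0.01 and 0.27. At 4 weeks r was 0.067, 0.075 and 0.034, with rho of 0.04 in each class. Genes are not independent replicates, so no p-value is given. The Müller-like r at 2 weeks was 0.0450 without nuclei of over 25% rod chromatin.

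**Figure D5:**
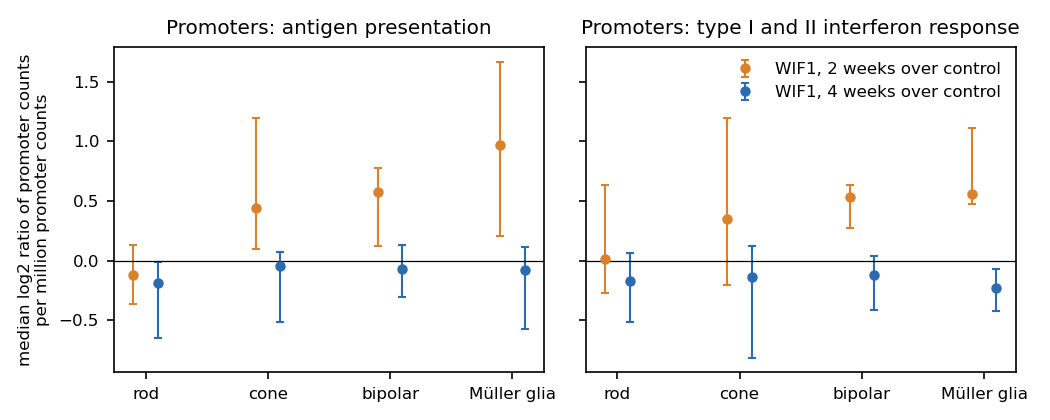
Median log2 ratio to control of promoter counts, in CPM of all promoter counts, for antigen presentation (left) and interferon response genes (right) in 4 classes, with 95% intervals over list members. At 2 weeks antigen presentation promoters were at 0.58 in bipolar-like and 0.97 in Müller-like nuclei, and at 4 weeks at −0.07 and −0.08.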

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

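All tests of explanations in this part were chosen after the results were seen.

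For the antigen presentation RNA, higher in the 2-week library by the list median in each of the 6 classes measured, free RNA from other cells as the whole source of the class I genes in bipolar-like nuclei is argued against, since their excess CPM there was 5.90 times (5.18 to 6.82) that in rod-like nuclei. For immunoglobulin genes, Igkc of which had 50.9% of its bipolar-like UMIs in 1 nucleus, this ratio was 1.09 in bipolar-like, 0.411 in cone-like, 0.215 in Müller-like and 0.177 in amacrine-like nuclei. Rod-like nuclei are the reference of these ratios, so free RNA as the whole source stays open in them. Among bipolar-like nuclei of at most 1% mitochondrial UMIs the median log2 ratio of 9 class I genes was 3.05 (1.39 to 4.11). Over all bipolar-like nuclei it was 2.85 (0.76 to 3.91) for 15 class I genes. These values argue against a lower mitochondrial share as the whole source for class I genes in bipolar-like nuclei. Whether less cytoplasm could raise these genes at all was not tested. Higher promoter accessibility stays open, since class I promoters there stood at 0.58 (0.12 to 1.08) at peaks shared by the 3 libraries and 0.50 (0.090 to 1.07) per covered kb, but all promoters of the list at 0.12 (−0.021 to 0.63) per covered kb. For class II genes free RNA and expression cannot be told apart in bipolar-like nuclei, with a ratio of 0.616 (0.478 to 0.780), or in Müller-like nuclei, with 3.4 (2.63 to 4.30) but 2.61 (1.98 to 3.35) without the highest nucleus of each gene, short of the bound of 2 set for this test, and 72.5% of Cd74 UMIs in 5 nuclei, nor for either class injection, vector and WIF1, because 0 libraries came from eyes given a control vector, and a biological response to any of them may be present.

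Amacrine-like nuclei had lower shares in both WIF1 libraries, with ratios of 0.465 and 0.243, or 0.701 and 0.577 when named by the highest marker score. Loss of shallow nuclei at the UMI floor was not decided. The share ratio with nuclei from 200 UMIs, each named by likelihood, was 0.408 (0.347 to 0.479) and 0.215 (0.174 to 0.265) at 2 and 4 weeks. The control held 0 barcodes under 500 UMIs, against 3400 and 294, so this lower floor added nuclei to the WIF1 libraries alone. The ratio of 0.944 at 2 weeks among nuclei of at least 1000 UMIs came with a floor that left 729 of 5991 rod-like but 198 of 212 amacrine-like nuclei. A lower yield alike in all amacrine-like clusters would leave cluster 14 over the other clusters at 1 time the control, and it stood at 0.298 (0.193 to 0.443) and 0.270 (0.144 to 0.442). Cluster 14 was taken because it held the most amacrine-like nuclei in the control, a choice that leans toward a fall. A yield that differs between cell types stays open. Dissection or pooling of eyes cannot be told apart from WIF1 with 1 library per group. A loss of some amacrine types may be present and was not tested. Sub-clusters with Gad1 and Gad2 held 41, 6 and 1 (14.1), 24, 20 and 9 (14.6) and 14, 6 and 8 nuclei (14.10). Others with both genes held 12, 4 and 0 (14.12) and 9, 2 and 0 nuclei (14.5). Some sub-clusters with the same amacrine markers enriched differed by library in opposite ways. In cluster 20, with called doublets kept, such a pair held 14, 2 and 1 nuclei, and 2, 30 and 3. In cluster 22 a pair held 17, 2 and 2 nuclei, and 13, 37 and 12. Few nuclei in a sub-cluster therefore do not by themselves show that a type was lost.

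Reactive-glia genes were higher in Müller-like nuclei of the 2-week library. Nuclei that carry rod chromatin as the whole cause are argued against by a median log2 ratio of 0.51 (0.26 to 1.14) without nuclei of over 25% rod chromatin. Among nuclei of at most 1% mitochondrial UMIs the median was 1.03 (0.51 to 1.37) over 24 members. This limit left 50 of 131 Müller-like nuclei in the control and 222 of 283 at 2 weeks. A lower mitochondrial share as the whole cause is argued against. The limit was not combined with the one on rod chromatin, so a joint effect of the 2 stays open. Without the highest nucleus of each gene in each library the median was 1.11 (0.70 to 1.92). Whether a few nuclei held most UMIs stays open, since only 1 nucleus per gene was left out and the sparser control lost counts too. A reaction of Müller glia to injection, vector or WIF1 may remain, as a hypothesis found and tested on the same data.

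At both times 285 values were compared with the control: class shares, and the RNA and the promoters of a list in a class. Of these, 3 had intervals on opposite sides of no difference, and in each the difference between the times was not tested. RNA of rod phototransduction genes in endothelial-like nuclei had a median log2 ratio of −0.39 at 2 weeks and 0.29 at 4 weeks. RNA of rod origin was estimated there at 23.4% of UMIs in the control, 15.2% at 2 weeks and 34.8% at 4 weeks. Promoters of the same genes in Müller-like nuclei stood at −1.59 and 0.29, and interferon response promoters in Müller-like nuclei at 0.56 and −0.23, or 0.25 and 0.16 without nuclei of over 25% rod chromatin. Of 16 unnamed groups of nuclei looked at, 2 had an interval of their 2-week share wholly above that of the control, without a test. Sub-cluster 13.2, with immunoglobulin and class II genes, held 20 nuclei at 2 weeks, 1 in the control and 0 at 4 weeks. Sub-cluster 21.3, with Igfbp5, Pdgfra, Gfap and Lcn2, held 18 nuclei at 2 weeks, 1 in the control and 11 at 4 weeks, and 21, 7 and 13 with called doublets kept.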

How the results depend on the processing

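Alternatives chosen after the data were seen were naming by likelihood from 200 UMIs, sub-clusters named from 3 markers, leaving out nuclei of over 25% rod chromatin, at most 1% mitochondrial UMIs, and promoter peaks shared by all 3 libraries. The motif comparison was not run, for want of a genome sequence. Of 517 values of main results under alternatives, 453 stayed within the interval of the main value, 58 moved out of it and 6 reversed. Of 1608 values of single genes and other lists 1390 stayed, 201 moved and 17 reversed. Counts of genes were compared by size. A value was called reversed only if the main interval excluded no difference, so some values called moved changed sign, and some that stayed may have too. Some could not move by construction, such as correlations scaled to all ATAC counts. No paired analysis was possible because no labels pair the eyes or libraries. TMM scaling took the median log2 ratio of all genes in rod-like nuclei at 2 weeks from 0.05 to −0.05, and in endothelial-like nuclei from −0.10 to −0.22, and thinning took that of amacrine-like nuclei at 4 weeks from −0.03 to 0.13. Except where a sentence says otherwise, the cause was not tested. Ratios are to control and pairs of values are at 2 and 4 weeks.

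Per 1000 nuclei, without correction for ATAC depth, the Wif1 promoter ratios were 1.75 (1.53 to 2.01) and 1.14 (0.986 to 1.33). Among nuclei of at least 1000 UMIs share ratios were 0.944 for amacrine-like and 3.43 for Müller-like nuclei at 2 weeks, 0.412 and 1.07 for rod-like, 1.60 and 0.957 for bipolar-like, and 2.02 and 1.1 for cone-like nuclei. With each library clustered alone they were 0.579 and 0.319 for amacrine-like, 1.04 and 0.866 for Müller-like, and at 4 weeks 1.09 for rod-like and 0.925 for bipolar-like nuclei. Named by the highest marker score they were 0.701 and 0.577 for amacrine-like, 0.846 and 0.917 for bipolar-like, and 1.0 for rod-like nuclei at 2 weeks. As shares of nuclei other than rods, which raises every ratio by construction, they were 0.567 and 0.317 for amacrine-like, 0.945 and 1.03 for bipolar-like, 1.20 and 1.19 for cone-like, and 2.05 for Müller-like nuclei at 4 weeks. At Leiden resolution 2 the Müller-like ratio at 2 weeks was 2.30, and by likelihood from 200 UMIs it was 2.20, with 0.703 for bipolar-like nuclei.

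Without nuclei of over 25% rod chromatin, Müller-like share ratios were 2.53 and 2.15, reactive-glia genes stood at 0.51 at 2 weeks and −0.086 at 4 over 2 weeks, and the promoter and RNA correlation at 2 weeks was 0.0450. Müller-like promoter medians were then 0.25 and 0.16 for interferon and 0.26 at 4 weeks for antigen presentation genes, heat shock genes stood at 0.081 and Cntn5 at −0.97, both at 4 weeks.

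Among nuclei of at most 1% mitochondrial UMIs, Tcf4 stood at −0.16 and −0.11 in bipolar-like nuclei. At 4 weeks Cabp2 stood at 0.41 in bipolar-like and Psmb8 at 0.12 in Müller-like nuclei. Medians were 0.97 for interferon genes in bipolar-like nuclei at 2 weeks and 0.22 in Müller-like at 4 weeks, −0.71 and 0.55 for antigen presentation in rod-like and bipolar-like nuclei at 4 weeks, −0.33 for Wnt target genes in Müller-like nuclei at 4 weeks, −1.71 for cholesterol genes in Müller-like nuclei at 2 weeks and 0.049 for rod genes in rod-like nuclei at 2 weeks. Ribosomal protein genes stood at 0.39 and 0.084 in bipolar-like nuclei and 0.051 in Müller-like nuclei at 4 weeks, and mitochondrially encoded genes there at 0.042. Of the 60 gene and class pairs past 2-fold among the highest and lowest at 2 weeks, 40 were measured under this limit and 39 stayed past it, and of the 46 at 4 weeks 26 were measured and 18 stayed. At 4 weeks 25 of 35 measured stayed with counts thinned to 1000 per nucleus, and 20 have at least 100 UMIs and stayed.

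With counts thinned, Hspa1a stood at 0.34 in bipolar-like nuclei, and Psmb8 at 0.45, Trnp1 at −0.55 and Wnt5b at −0.28 in Müller-like nuclei, all at 4 weeks. With doublets kept Cntn5 stood at −0.36 and Trnp1 at −0.86 in Müller-like nuclei at 4 weeks. As a mean over nuclei, Müller-like medians were 0.24 for interferon and −0.042 for cholesterol genes at 4 weeks, and −0.94 for interferon and −0.34 for reactive-glia genes at 4 over 2 weeks. TMM put rod genes in rod-like nuclei at −0.24 at 2 weeks. With RNA of rod origin subtracted, which lowers rod genes in each library by construction, rod genes in bipolar-like nuclei stood at 0.30 at 2 weeks, as a ratio of the counts left. Müller-like interferon and reactive-glia genes then stood at −0.89 and −0.25 at 4 over 2 weeks. With list members of at least 30 UMIs, interferon genes in rod-like nuclei stood at −0.37 at 4 over 2 weeks. Requiring 50% overlap gave 45.1%, 87.6% and 86.2% shared peaks. From 100 promoter counts the correlations were 0.0470 in bipolar-like nuclei at 4 weeks and 0.275 in Müller-like nuclei at 2 weeks, and scaled to all ATAC counts Müller-like interferon promoters stood at 0.35 at 2 weeks.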

Other observations

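Genes of the Y chromosome were read at similar levels in all 3 libraries, with Ddx3y at 83.5, 83.9 and 84.1 CPM over kept nuclei of the control, 2-week and 4-week libraries. Kdm5d stood at 56.4, 48.2 and 55.1 CPM, and Xist, which female cells express from the inactive X chromosome, held 1, 4 and 3 UMIs.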
